A study of Mus musculus with 93 samples.

How the data were processed

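RNA was measured by RNA sequencing (Smart-seq2 libraries, per the labels) in mouse embryos or embryo pieces labelled Tfap2c control or Tfap2c mzKO. The label mzKO is commonly read as a maternal and zygotic knockout, and the labels do not spell it out. The 56 RNA libraries form 14 groups, a control and a mzKO group at each of 7 stages. The series lists 93 samples. The other 37, made by CUT&RUN, ATAC-seq or ChIP-seq, have no processed file per sample and were not analysed, and 2 CUT&RUN samples among them could not be placed in a group from their labels.

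Each library has a table deposited by the authors with 1 FPKM value (mapped fragments scaled to transcript length and to library size) for each of 25174 gene symbols. The authors' notes name TopHat2 2.0.11, Cufflinks 2.2.1, Bowtie2 2.3.5, deepTools 3.3.1 and the mouse build mm9, without saying which step each tool served. The annotation available here follows another build, so no gene positions are given. Of the gene symbols, 25028 are in its gene table, 92 are there only as synonyms and 54 are not there. The order of genes differed in 13 files, so files were joined by symbol. No 2 libraries were identical, and the highest correlation between 2 libraries of a group was 0.985. The files hold no read counts, so the number of reads per library is unknown and no counting intervals are given. A relative depth was estimated from the most common ratio of low FPKM values between each library and a reference library. It is given as a percent of the deepest library.

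Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with a trend and statmod 1.5.0 installed). Each stage was fitted alone with genotype as the only term. A gene was tested when its FPKM was at least 1 in as many libraries as the smaller group holds. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called changed, and all limma tests were two-sided. The p-values measure the spread between samples. The FPKM values were not scaled further in the main comparison. Fold values are ratios of mean FPKM, and log2 differences are mzKO minus control with the standard error of the fit. The difference between 2 genotype effects was tested as an interaction, for the 8-cell embryo and the ICM and for both E6.5 tissues. Shared genes between stages were tested with Fisher's exact test over the genes tested at both stages.

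The comparisons, their tests, the rule for named genes and 31 gene lists were fixed before the data were examined. Lists with at least 5 tested genes were compared with all other genes by camera (preset correlation between genes of 0.01), again with an estimated correlation, and by fry. Camera asks whether a list moves more than the remaining genes, and fry whether a list moves 1 way on balance. A list of histone genes found no gene under the symbols in these files and was not tested. Named genes are Tfap2c, Nr5a2, Cdx2 and Sox2 at each stage, then the 10 largest rises and 10 largest falls among changed genes whose groups do not overlap, skipping predicted genes, small RNA genes and microRNAs, and up to 4 genes with the smallest p from each list described. Where no gene passed, the 5 genes with the smallest p are named. Lists are described when they passed camera, when at least 3 of their genes changed, or when they mark the tissue sampled.

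Headers inside the deposited files split the libraries of 4 stages into series. The 8-cell libraries fall into a first series (3 control, 1 mzKO) and a second (2 and 2). The ICM libraries fall into 3 series (1 and 1, 2 and 2, 2 and 2). The epiblast libraries fall into a first series (3 and 5) and a second (2 and 5), and the ExE libraries into a first (2 and 3) and a second (4 and 2). The headers name B6 for both controls of the second ICM series and WT for all controls of the second E6.5 series, where the labels say Tfap2c control, so these controls may come from another strain or line than the others. Replicate numbers did not pair the libraries: at no stage with at least 3 pairs were all libraries of the same number more alike than others.

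Alternatives chosen in advance were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling of the libraries, 1 fit of all 14 groups, the replicate number as a block, limma array weights, an estimated correlation in camera and leaving out each library in turn. Chosen after seeing the data were a term for series, each series alone (for changed genes and Tfap2c), crossed replicate numbers, a correlation between pieces of the same embryo and leaving out libraries whose marker genes or profile stood apart. The method was tested on simulated data with 200 genes changed in each comparison. With 2 libraries in each group (2-cell, 4-cell, TE) it called 0% of genes changed 4-fold. It called 74% at the 8-cell stage, 71% in the ICM, 90% in the epiblast and 92% in the ExE. For a 2-fold change it called 27%, 13%, 31% and 25% at those 4 stages. Genes simulated without a change and still called numbered 6, 4, 11 and 4 there. A simulated list moved 2-fold was called at every stage with the preset correlation, and with the estimated correlation at every stage except the 3 with 2 libraries in each group. With the preset correlation 1 list that was not moved was also called at the 4-cell and at the 8-cell stage. Simulated genes varied independently of each other, so lists whose genes vary together were not tested.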

Results

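Gene expression was measured in mouse embryos at the 2-cell, 4-cell and 8-cell stages, in the inner cell mass (ICM) at E3.5, the trophectoderm (TE) at E4.5, and the epiblast and extraembryonic ectoderm (ExE) at E6.5. Control and mzKO libraries numbered 2 and 2 at the 2-cell stage, 2 and 2 at the 4-cell stage, 5 and 3 at the 8-cell stage, 5 and 5 in the ICM, 2 and 2 in the TE, 5 and 10 in the epiblast, and 6 and 5 in the ExE. Per the labels, wild-type E3.5 ICM came from 8-cell embryos kept in culture, and TE came from embryos flushed at E4.25. The sum of FPKM per library ran from 184988 to 579586 with a median of 334207, and 7421 to 10505 genes reached an FPKM of 1.

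Tfap2c, the gene named in the genotype, encodes a transcription factor of the AP-2 family that is active in cleavage-stage embryos and trophoblast. Its mean FPKM was 21.4 ± 1.86 (SD, n = 2) in control and 9.70 ± 1.26 (n = 2) in mzKO libraries at the 2-cell stage, and 30.3 ± 1.91 against 5.52 ± 0.61 at the 4-cell stage. The groups did not overlap at either stage, and the limma adjusted p was 0.542 and 0.589. From the 8-cell stage on, the groups overlapped, with 26.8 ± 8.67 against 22.2 ± 10.9 at the 8-cell stage, 26.5 ± 7.31 against 21.8 ± 9.67 in the ICM and 23.1 ± 1.83 against 23.1 ± 0.27 in the TE. The log2 difference was -1.09 in the first and -0.17 in the second series at the 8-cell stage, and -0.51, -0.78 and 0.22 in the 3 series of the ICM. In the ExE it was 52.8 ± 39.8 in control and 92.8 ± 23.2 in libraries labelled mzKO (log2 difference 1.08 ± 0.40, adjusted p = 0.054). That difference was -0.26 in the first series and 1.81 in the second, where controls were low. In the epiblast Tfap2c was near the detection floor, at 1.06 and 0.76. A single value per gene cannot separate transcripts with and without a deleted part, so the groups below are named as labelled.

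**Figure D1:**
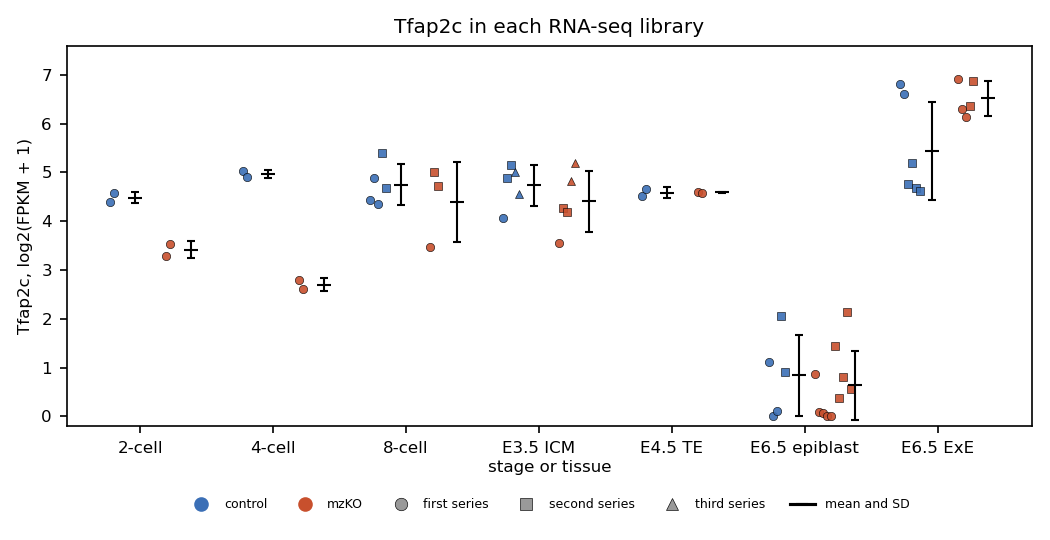
Tfap2c in each library, as log2(FPKM + 1), by stage and labelled genotype, with bars for the mean and SD on that scale. At the 2-cell and 4-cell stages all mzKO libraries lie below all controls, and from the 8-cell stage on the groups overlap.

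At the 2-cell stage, oocyte transcripts and genes of the 2-cell program tended to be higher in mzKO libraries. This comparison covers the start of development, when Tfap2c was lower in mzKO libraries but not absent. Of the maternal oocyte transcripts, 34 of 37 had a positive log2 difference (median 0.67, camera adjusted p = 1.06e-07, adjusted p = 0.909 with an estimated correlation). Of the genes typical of the 2-cell embryo, 23 of 26 did (median 0.74, camera adjusted p = 0.000492, adjusted p = 0.909 with an estimated correlation). Oocyte genes of the NLRP family and of the maternal complex under the oocyte membrane were among them. Nlrp14 was at 53 ± 4.09 FPKM in control and 139 ± 24.6 in mzKO libraries, Ooep at 16.0 ± 3.93 and 55.1 ± 14.6, and Nlrp4f at 87.8 ± 1.10 and 199 ± 10.8. Oosp1, which encodes an oocyte-secreted protein, was at 133 and 294. In the 2-cell group, Spz1, a transcription factor gene, was at 3.81 and 26.1, and Arg2, which encodes a mitochondrial arginase, at 22.2 and 73.4. No gene of these lists passed over all genes, while 7 oocyte and 5 two-cell-stage genes were higher when adjusted over the list alone. All genes had a median log2 difference of 0.12 at this stage, which scaling brought to 0.01.

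Germline genes that DNA methylation keeps silent had a median of 0.66 at the 2-cell stage (18 genes, camera adjusted p = 0.00603, adjusted p = 0.909 with an estimated correlation), among them the spermatogenesis genes Mael at 18.9 and 47.3 FPKM and Brdt at 219 and 390. Ribosomal protein genes had a median of -0.16 (70 genes, camera adjusted p = 0.0122, adjusted p = 0.909 with an estimated correlation). No germline gene and no ribosomal gene passed over all genes, and adjusted over the list alone 0 germline genes and 1 ribosomal gene (Rpl29) were higher. Of 10612 genes tested, 3 changed, all higher. Snhg9, a host gene of small nucleolar RNAs, rose from 12.4 ± 1.71 to 111 ± 2.47 (log2 difference 3.07 ± 0.28, adjusted p = 0.0498). The others, Snora75 (listed at 0 in controls, 40.3 in mzKO) and Snora7a (0 and 39.0), are small nucleolar RNA genes named here after their values were seen. After scaling limma called 0 genes. Nr5a2, which encodes a nuclear receptor named in the title of the series, was at 54.0 and 36.8. Cdx2 and Sox2 were below the level tested at the 2-cell and 4-cell stages.

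At the 4-cell stage, pluripotency genes were lower on balance in mzKO libraries. The naive pluripotency list had a median log2 difference of -0.82 (24 genes, camera adjusted p = 0.0012, adjusted p = 0.772 with an estimated correlation). Spic, an ETS-family transcription factor gene of the early embryo, was at 603 ± 273 FPKM in control and 242 ± 29.3 in mzKO libraries. Tcl1, a co-activator of AKT kinase, was at 74.4 and 8.00, the adhesion gene Pecam1 at 35.1 and 9.46, and Klf5, a factor for both first lineages, at 70.2 and 25.9. Trophoblast stem cell genes had a median of -0.73 (13 genes, camera adjusted p = 0.017, adjusted p = 0.705 with an estimated correlation), with the surface antigen gene Ly6a at 37.4 and 6.08. Cell cycle genes had a median of -0.33 (34 genes, camera adjusted p = 0.0059, adjusted p = 0.705 with an estimated correlation), with the centromere histone gene Cenpa at 124 and 46.2.

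2 lists were higher at the 4-cell stage. Surface ectoderm and amnion genes had a median of 0.89 (8 genes, camera adjusted p = 0.0357, adjusted p = 0.705 with an estimated correlation), with the keratin gene Krt18 at 15.1 and 78.8. Genes of the decidua and uterus had a median of 1.50 (8 genes, camera adjusted p = 0.000314, adjusted p = 0.705 with an estimated correlation), with Ltf, the gene of the secreted protein lactotransferrin, at 11.9 and 77.6. Blood and immune cell markers, which come from other cells, did not pass (median 0.34, camera adjusted p = 0.242) but summed to 2613 FPKM in control 1 and 1813 in mzKO 1, against 41.0 in control 2 and 55.7 in mzKO 2. Genes of the 2-cell program (median 0.05, camera adjusted p = 0.831) and oocyte transcripts (median -0.06, adjusted p = 0.425) did not pass. Without control 2 camera called 0 lists, with medians of -0.30 for naive pluripotency, -0.89 for trophoblast stem cell, -0.37 for cell cycle, 0.64 for surface ectoderm and 1.15 for decidua genes. Of 10312 genes limma called 0 changed, with 731 at an unadjusted p below 0.05. Adjusted over the list alone, 1 gene each passed in the trophoblast stem cell (Ddah1, lower), surface ectoderm (Krt18, higher) and decidua (Ltf, higher) lists and 0 in the others. The 5 genes with the smallest p, none past the threshold, were BC028528, the defensin gene Defb25, the glycine cleavage gene Amt, Wfdc17 and the urea transporter gene Slc14a1. Nr5a2 was at 67.0 and 52.9.

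At the 8-cell stage, pluripotency factors were lower in libraries labelled mzKO, and Nr5a2 fell with them. This comparison covers the stage before the ICM and TE separate. Nanog, a core pluripotency factor, fell from 28.9 ± 11.2 FPKM (n = 5) to 7.42 ± 2.70 (n = 3; log2 difference -1.82 ± 0.36, adjusted p = 0.0255), and Tfcp2l1, a factor of the naive state, from 31.8 to 3.57 (-2.68, adjusted p = 0.0168). Nr5a2 fell from 41.9 ± 5.87 to 17.8 ± 5.77 (-1.22 ± 0.27, adjusted p = 0.0382), with -1.59 in the first series and -0.92 in the second. For Nr5a2 at the 8-cell stage the adjusted p was 0.0517 after scaling and ran from 0.00111 to 0.148 over all alternatives. The Nr5a2 call held without mzKO library 2 and was lost without any of the other 7 libraries, where the difference stayed between -1.28 and -1.09. The Nanog call was lost without control 4 or 5 or any mzKO library, where the difference for Nanog at the 8-cell stage stayed between -1.97 and -1.51. Dppa3, a maternal factor that protects DNA methylation, fell from 4573 to 2054, a call that each leave-out kept. Gdf3, a TGF-beta family ligand, fell from 8.45 to 0.58, and Fgfr2, the FGF receptor of the trophectoderm and primitive endoderm lineages, from 9.27 to 1.22 (adjusted p = 0.0297). Single leave-outs also ended the calls of Tfcp2l1 (mzKO 1 or 3), Fgfr2 (control 3, 4 or 5, mzKO 1 or 3) and Gdf3 (each library except control 2).

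Among the largest falls at the 8-cell stage, Smpdl3a, a lysosomal phosphodiesterase gene, went from 68.0 ± 12.9 to 0.19 ± 0.23 FPKM (-5.85, adjusted p = 4.62e-07), with -6.16 and -5.62 in the first and second series. Crip1, a LIM-domain gene, fell from 160 to 2.46, Ly6a from 324 to 25.3, and Tfeb, the transcription factor of lysosome biogenesis, from 17.1 to 1.49. Dap, Pinlyp, Ctrl, Tspan1 and Cthrc1 fell by 3.03 to 4.01 on the log2 scale, and Cnmd fell from 9.28 to a listed value of 0. Among the rises, Trmt61b, a gene for mitochondrial tRNA methylation, went from 61.3 to 230 (1.92), the glutathione transferase gene Gsta2 from 6.82 to 39.9, and Cdc42ep5, an effector of CDC42, from 35.2 to 129. Fgf5, a marker of the later epiblast, rose from 1.11 to 6.47. Serinc2, Mettl8, Ecscr, Slc10a3, Usp17lb and Zfp623 also rose, from control levels of at most 3.64.

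Of 8890 genes tested at the 8-cell stage, 157 changed, 48 higher and 109 lower. Every one had the same sign in both series, and 142 differed at least 2-fold in both. These genes were called on both series together, so the selection partly builds in this agreement. With a series term 429 changed, all 157 included, and after scaling 202 (81 higher, 121 lower). The share of calls that were higher was 30.6%, and 40.1% after scaling. In 13.0% of tested genes the groups did not overlap, against 3.57% by chance. The count was 28 without mzKO library 1, 91 without mzKO 2, 53 without mzKO 3, 102 without control 1, 46 without control 4 and 49 without control 5.

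Camera called 5 lists at the 8-cell stage, 2 lower and 3 higher, but other splits of the libraries gave as many, so chance was not excluded for them. The naive pluripotency list had a median of -0.66 (25 genes, 5 lower over all genes, 9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00132, adjusted p = 0.849 with an estimated correlation). Trophoblast stem cell genes had a median of -0.40 (17 genes, 2 lower, 3 lower adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.849 with an estimated correlation). Its call was lost without mzKO library 1 (median 0.08), control 2 (-0.62) or control 4 (-0.38). Oxidative phosphorylation genes had a median of 0.34 (87 genes, 78 positive, camera adjusted p = 2.77e-09, adjusted p = 0.849 with an estimated correlation), and Cox5a, a subunit of cytochrome oxidase, rose from 793 to 1288, the only one to pass over all genes or adjusted over the list alone, a call lost without control 4 or 5 or any mzKO library. Ribosomal protein genes had a median of 0.23 (74 genes, none past either adjustment, also adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.849 with an estimated correlation). The p53 targets had a median of 0.61 (19 genes, 0 over all genes and 1 higher adjusted over the list alone, camera adjusted p = 0.0068, adjusted p = 0.849 with an estimated correlation), with Ei24 at 23.4 and 61.3. Without mzKO library 3 the p53 call was lost (median 0.34), and the ribosomal call without mzKO 1 (0.14) or control 4 (0.19). Trophectoderm genes had a median of -0.25 (17 genes, 1 lower, 2 lower adjusted over the list alone, camera adjusted p = 0.538). Cdx2, a trophectoderm factor, was at 2.14 and 1.33 and did not pass, and Sox2 was below the level tested.

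In the E3.5 ICM, epiblast genes were lower and primitive endoderm genes higher in libraries labelled mzKO. The ICM gives rise to these 2 lineages. Nanog, needed for the epiblast, fell from 105 ± 24.0 FPKM to 20.8 ± 18.0 (n = 5 and 5; log2 difference -2.57 ± 0.41, adjusted p = 0.00626), with -3.64, -1.55 and -3.05 in the 3 series. Gata4, a primitive endoderm factor, rose from 0.63 ± 0.86 to 11.1 ± 8.27 (2.82 ± 0.46, adjusted p = 0.00673), with 2.72, 3.31 and 2.37 in the 3 series. Spic fell from 87.4 to 10.5 (-3.47), the Nodal co-receptor gene Tdgf1 from 47.3 to 1.27, and Klf2, a factor of naive pluripotency, from 13.4 to 1.19 (-2.57, adjusted p = 0.0364, not past the threshold after scaling). The naive pluripotency list was negative for 24 of 24 genes (median -0.86, 4 lower over all genes, 10 lower adjusted over the list alone, camera adjusted p = 1.13e-05, adjusted p = 0.115 with an estimated correlation). The primitive endoderm list had a median of 0.73 (14 genes, 1 higher, 3 higher adjusted over the list alone, camera adjusted p = 6.86e-10, adjusted p = 0.056 with an estimated correlation). The laminin gene Lamb1 was at 14.8 and 31.5 (adjusted p = 0.0847) and the endoderm factor Sox17 at 1.67 and 4.5, neither past the threshold. In limma with a series term the adjusted p was 0.0454 for Lamb1 and 0.135 for Sox17. After scaling it was 0.0272 and 0.221. Leaving out any 1 library kept the calls of Nanog, Gata4, Spic, Tdgf1 and both lists. Visceral endoderm genes did not follow the primitive endoderm list (7 genes, median 0.07, 0 over all genes, 1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.756), and the sum of their FPKM was 164 to 439 in controls and 74.1 to 159 in mzKO libraries. Lars2, the mitochondrial leucyl-tRNA synthetase gene whose reads often include mitochondrial ribosomal RNA, was at 1959 ± 1070 and 5140 ± 2169 (1.54, adjusted p = 0.11), with 1.60, 2.64 and 0.42 in the 3 series.

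**Figure D2:**
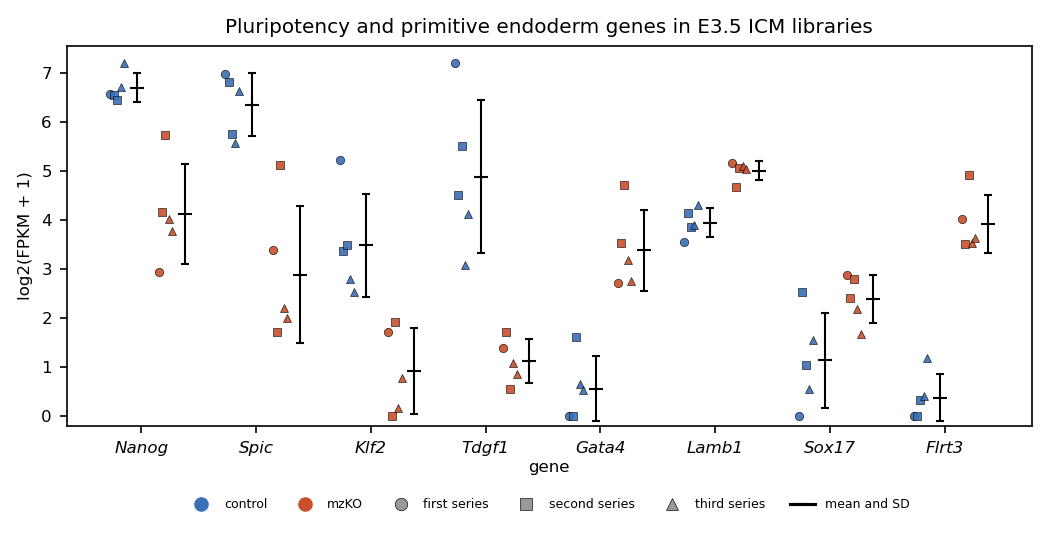
Pluripotency genes (Nanog, Spic, Klf2, Tdgf1) and endoderm genes (Gata4, Lamb1, Sox17, Flrt3) in each E3.5 ICM library, as log2(FPKM + 1), with bars for the mean and SD, colour for labelled genotype and marker for series. Nanog averaged 105 FPKM in controls and 20.8 in libraries labelled mzKO, and Gata4 0.63 and 11.1.

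Among the largest rises in the ICM, Flrt3, a membrane protein gene of endoderm, went from 0.37 ± 0.53 to 15.4 ± 7.98 FPKM (3.54, adjusted p = 0.00136), the intermediate filament gene Vim from 1.65 to 29.9, and the WNT inhibitor gene Dkk1 from 0.34 to 9.10. Mgst2 (2.41 to 38.7), Akr1c13 (2.14 to 16.1) and Gpx2 (15.2 to 114), which encode enzymes for glutathione and carbonyl compounds, rose as well, as did the water channel gene Aqp8 (7.28 to 88.7), Il33 and Ramp2. Falls included Aqp3, a water channel gene of the blastocyst (64.5 to 7.15), Ezr, which encodes the microvillus protein ezrin (26.5 to 4.89), the galectin gene Lgals1 (289 to 42.5) and the glucose transporter gene Slc2a3 (88.9 to 27.5). Mt4, Il2rg, Smpdl3a, Pinlyp, Fxyd4 and Ttyh2 also fell. The calls of Slc2a3, Fxyd4 and Ttyh2 were lost after scaling (adjusted p = 0.2, 0.117 and 0.152). Asns, a target of the integrated stress response, rose from 14.9 to 53.1. The calls of Klf2, Akr1c13, Gpx2, Ramp2, Slc2a3, Pinlyp, Fxyd4, Ttyh2 and Asns were lost when control 2 was left out, and after other single leave-outs, without a change of direction.

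Of 9323 genes tested in the ICM, 73 changed, 21 higher and 52 lower. All had the same sign in all 3 series and 63 differed at least 2-fold in each, which is partly built in, since all series entered the call. The median log2 difference of all genes was -0.30, and scaling brought it to -0.004. After scaling 42 genes changed, 25 higher and 17 lower, so 28.8% of calls were higher before and 59.5% after. The naive pluripotency median relative to other genes was then -0.52 and that of primitive endoderm 1.07. With a series term 217 changed, all 73 included. The groups did not overlap in 4.63% of genes, against 0.794% by chance. The count was 26 without control 2, 37 without control 3, 43 without mzKO 2 and 33 without mzKO 5.

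The primed epiblast and germ cell lists, which share members with the naive list, were also lower in the ICM. Tdgf1, the 1 lower gene of the primed epiblast list, and Nanog and Klf2, the 2 lower genes of the germ cell list, are members of the naive list too. Primed epiblast genes had a median of -0.92 (15 genes, 1 lower, 4 lower adjusted over the list alone, camera adjusted p = 0.00424, adjusted p = 0.0728 with an estimated correlation), and germ cell genes -1.01 (7 genes, 2 lower, 3 lower adjusted over the list alone, camera adjusted p = 0.00424, adjusted p = 0.0728 with an estimated correlation). Polarity and junction genes had a median of -0.54 (25 genes, 1 higher and 2 lower, 1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0344, adjusted p = 0.417 with an estimated correlation). Oocyte transcripts had a median of -0.65 (9 genes, 0 over all genes, 3 lower adjusted over the list alone, camera adjusted p = 0.0485, adjusted p = 0.325 with an estimated correlation), with Khdc3 of the maternal complex at 491 and 256. Glycolysis genes had a median of -0.61 (14 genes, 1 lower, 2 lower adjusted over the list alone, camera adjusted p = 0.0212, adjusted p = 0.325 with an estimated correlation), among them the hexokinase gene Hk2 at 34.8 and 19. Their median was -0.46, -0.81 and -0.64 in the 3 series, where all tested genes were at -0.69, -0.27 and -0.14. In the first series the list thus lay above all genes. Trophectoderm genes did not pass (23 genes, median -0.39, and -0.03 after scaling, 0 over all genes, 1 lower adjusted over the list alone, camera adjusted p = 0.153). In that list the keratin gene Krt18 was at 695 and 219 and Cdx2 at 20.3 and 8.55. Nr5a2 was at 8.25 and 7.21 and Sox2 at 6.05 and 2.67, and neither passed.

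Camera called 4 further lists in the ICM higher and oxidative phosphorylation lower than other genes. All tested genes had medians of -0.69, -0.27 and -0.14 in the 3 series. The p53 and cholesterol synthesis medians lay above these in each series. Of the 5 lists only oxidative phosphorylation kept its sign in all 3 series, but in the second it lay above all genes. The p53 targets had a median of 0.43 (20 genes, 0 over all genes, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.48e-05, adjusted p = 0.33 with an estimated correlation), with the apoptosis gene Pmaip1 at 3.88 and 14.8. Their median was -0.49, 0.47 and 0.75 in the 3 series. Stress response genes had a median of 0.03 (15 genes, 1 higher also adjusted over the list alone, camera adjusted p = 0.0181, adjusted p = 0.327 with an estimated correlation), and 0.97, -0.63 and 0.34 in the 3 series. Cholesterol synthesis genes had a median of 0.08 (23 genes, camera adjusted p = 0.00424, adjusted p = 0.46 with an estimated correlation), oxidative phosphorylation genes -0.37 (83 genes, camera adjusted p = 0.00955, adjusted p = 0.567 with an estimated correlation) and ribosomal protein genes -0.03 (72 genes, camera adjusted p = 0.00824, adjusted p = 0.617 with an estimated correlation). None of these 3 lists had a gene past the threshold over all genes or adjusted over the list alone. Ribosomal genes had a negative median and mean, while camera called them higher than the remaining genes. After scaling their median was 0.31 and that of oxidative phosphorylation -0.01. In the 3 series the medians were -0.30, 0.31 and 0.11 for cholesterol synthesis, -0.96, -0.08 and -0.32 for oxidative phosphorylation and -0.74, 0.43 and -0.13 for ribosomal genes.

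9 genes were lower in libraries labelled mzKO both at the 8-cell stage and in the ICM, against 0.536 by chance among 7967 genes (Fisher's exact test, two-sided adjusted p = 1.21e-08). The number was 2 without ICM control 2 or 3, 3 without 8-cell mzKO 1 or ICM mzKO 2 or 5, 4 without 8-cell control 4 or 5 or ICM mzKO 4, and 5 without mzKO 3 of either stage, above chance each time. They were Nanog, Smpdl3a, Pinlyp, Ttyh2, Ccdc160, Etfb, Grn, Mfsd1 and Stard10. Grn (progranulin) and Smpdl3a encode lysosomal proteins, Stard10 a lipid transfer protein and Etfb an electron carrier of mitochondria. No higher gene was shared (0.0552 by chance, adjusted p = 1). With the ExE, the 8-cell stage shared 13 lower genes where chance gives 24.6 (adjusted p = 0.0148). This shortfall did not hold: it missed the threshold without 8-cell control 3 (11 genes), 4 (6) or 5 (6), 8-cell mzKO 3 (7) or ExE control 4 (10) and after scaling (5), and the number lay above chance without 8-cell mzKO 1 (6) and with no filter (5). It was 7 without 8-cell mzKO 2 and 8 without ExE mzKO 1, still below chance. The ICM and the ExE shared 13 where chance gives 11 (adjusted p = 0.713), and 3 without ICM control 2 or mzKO 5, 4 without ICM control 3, 5 without ICM control 4 or mzKO 2 and 8 without ICM mzKO 3 or 4. Each shared 1 higher gene with the ExE, Cdc42ep5 (adjusted p = 0.713) and Cited2 (adjusted p = 0.519).

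In the E4.5 TE no gene passed the threshold, and the trophectoderm list did not pass. Eomes, a factor of trophoblast self-renewal, was at 126 ± 4.24 FPKM in control and 27.5 ± 5.27 in mzKO libraries (n = 2 and 2), and Gata3, a trophoblast factor, at 375 and 213. The keratin gene Krt19 was at 47.9 and 344, and Cdx2 at 7.44 and 3.46. The trophectoderm list had a median of -0.62 (24 genes, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0908). Naive pluripotency genes had a median of -0.94 (13 genes, 1 lower adjusted over the list alone, camera adjusted p = 0.00289, adjusted p = 0.673 with an estimated correlation), with Nanog at 37.5 ± 29.6 in controls and listed at 0 in both mzKO libraries. The estimated relative depth was 57.3% and 53.2% in the TE controls and 36.8% and 24.0% in the TE mzKO libraries. Visceral endoderm markers, of a cell type other than TE, summed to 477 and 202 FPKM in the controls and to 47.5 and 43.7 in the mzKO libraries. Surface ectoderm genes had a median of -0.75 (8 genes, 0 adjusted over the list alone, camera adjusted p = 0.00308, adjusted p = 0.673 with an estimated correlation), with Tfap2a, the paralog of Tfap2c, at 37.4 and 16.9. Cholesterol synthesis genes had a median of -0.74 (22 genes, 0 adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.685 with an estimated correlation), with the sterol regulator gene Srebf2 at 8.68 and 0.38. Of 8569 genes limma called 0, with 640 at an unadjusted p below 0.05. The 5 genes with the smallest p, none past the threshold, were Mir295, the lipid phosphatase gene Plpp1 (14.2 and 252), the histone gene H2bc4 (249 and 10.3), Mir466p and the alcohol dehydrogenase gene Adh1. Nr5a2 was at 3.44 and 0.83, and Sox2 was below the level tested.

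In the E6.5 epiblast, no epiblast gene passed the threshold, at a stage where 31% of simulated 2-fold changes were called. Sox2, a factor of epiblast and neural cells, was at 11 ± 4.23 FPKM in control and 8.90 ± 4.42 in mzKO libraries (n = 5 and 10), and Otx2, an epiblast factor, at 67.4 and 96.2. In the first and second series the log2 difference was -0.78 and -0.06 for Sox2 and 0.29 and 0.77 for Otx2. The primed epiblast list had a median of 0.10 (28 genes, camera adjusted p = 0.773). Ribosomal protein genes had a median of -0.46 (76 genes, 66 negative, camera adjusted p = 5.07e-21, adjusted p = 0.238 with an estimated correlation) and oxidative phosphorylation genes -0.28 (86 genes, 70 negative, camera adjusted p = 1.08e-14, adjusted p = 0.376 with an estimated correlation). Among ribosomal genes, Rpl5 was at 17.5 and 9.31 and Rps25 at 216 and 111. Rps25 differed by -0.09 in the first series and -2.01 in the second. Germ cell genes had a median of -0.18 (11 genes, camera adjusted p = 0.0194, adjusted p = 0.238 with an estimated correlation), with Dppa3 at 2.79 and 1.31. The p53 targets had a median of 0.20 (22 genes, camera adjusted p = 0.0194, adjusted p = 0.238 with an estimated correlation), with the apoptosis gene Bax at 56.8 and 89.6. Glycolysis genes had a median of 0.20 (24 genes, camera adjusted p = 0.0194, adjusted p = 0.648 with an estimated correlation). No gene of these 6 lists passed, also adjusted over the list alone. Other splits of the libraries gave as many lists, so chance was not excluded for them. Visceral endoderm markers, of another cell type, summed to 148 to 299 FPKM in mzKO libraries 1, 4, 9 and 10 and to at most 95.8 in controls. Without those 4 libraries and control 4, the medians were -0.22 for ribosomal proteins at the E6.5 epiblast and -0.11 for oxidative phosphorylation at the E6.5 epiblast, both still past the threshold, and the p53 call was lost. Of 9841 genes limma called 0, with 132 at an unadjusted p below 0.05, and the groups did not overlap in 0.0305% of genes against 0.0666% by chance. The 5 genes with the smallest p, none past the threshold, were Snora75, Rps15a-ps4, the secreted hormone gene Stc2, Kank3 and Lsm5. Cdx2 and Nr5a2 were below the level tested.

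In the E6.5 ExE, 6 genes of the DNA methylation and imprinting list, all imprinted, rose and 5, also imprinted, fell in libraries labelled mzKO. H19, an imprinted noncoding RNA, rose from 309 ± 74.9 FPKM to 1108 ± 139 (n = 6 and 5; log2 difference 1.87 ± 0.22, adjusted p = 0.000743), with 2.28 in the first series and 1.64 in the second. The adjacent growth factor gene Igf2 rose from 119 ± 31.0 to 416 ± 55.4 (1.84), Meg3 from 3.90 to 38.8 (3.20) and the cell cycle inhibitor gene Cdkn1c from 12.9 to 39.8 (1.66). Other imprinted genes fell, with Phlda2, a brake on placental growth, going from 1539 to 379 (-1.85) and Snrpn from 50.9 to 11.2 (-2.13). Tfap2a rose from 0.20 ± 0.11 to 2.69 ± 0.94 (1.60 ± 0.23, adjusted p = 0.0015).

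**Figure D3:**
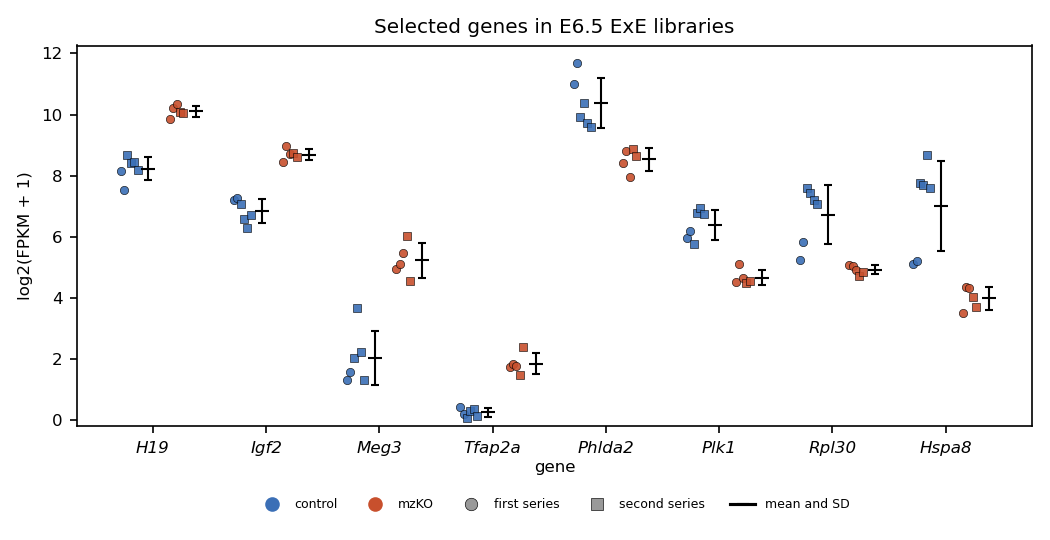
H19, Igf2, Meg3, Tfap2a, Phlda2, Plk1, Rpl30 and Hspa8 in each E6.5 ExE library, as log2(FPKM + 1), with bars for the mean and SD, colour for labelled genotype and marker for series. H19 averaged 309 FPKM in controls and 1108 in libraries labelled mzKO, and Plk1 87.4 and 24.6.

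Among the largest rises in the ExE were Lars2 (785 to 10180 FPKM), Camk2a, a calcium-dependent kinase gene (0.49 to 15.7), Ckap4, a receptor gene of the endoplasmic reticulum (1.23 to 13.2) and Basp1 (4.94 to 28.1). The immediate early gene Fos rose from 5.91 ± 2.17 to 127 ± 124, Atf3, a stress-induced factor, from 0.39 to 12.8, Klf2 from 1.19 to 20.4, Psors1c2 from 15.5 to 109 and Pou3f1, a factor of epiblast and neural cells, from 7.09 to 42.3. Among the largest falls were Folr1, a folate receptor gene (62.9 to 9.15), Cdh3, which encodes placental cadherin (23.8 to 3.81), Large2, a glycosyltransferase gene (32.1 to 3.45), the nucleoporin genes Nup93 and Nup62cl, and Aif1l, Reep6 and Crxos. Htr5b fell from 5.86 to a listed value of 0. Hspa8, the constitutive heat shock protein gene, fell from 181 to 15.2, with -1.09 in the first series and -4.07 in the second.

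Of 9634 genes tested in the ExE, 2853 changed, 325 higher and 2528 lower. The median log2 difference of all genes was -0.45 (-0.37 in the first series, -0.51 in the second), and scaling brought it to -0.07. After scaling 1403 genes changed, 677 higher and 726 lower, and 1049 of them had been called in the same direction before. The share of calls that were higher was 11.4% before and 48.3% after. With a series term 2764 changed, 2521 of them among the 2853. The sign was the same in both series for 2827 of the changed genes, and 687 differed at least 2-fold in both. Both series entered the call, so agreement in sign is partly set by the selection. The first series alone gave 26 changed genes (16 higher, 10 lower). Without controls 3, 5 and 6, which had the highest mean of primed epiblast genes, and without mzKO library 1, which did not, 186 changed (49 higher, 137 lower). The groups did not overlap in 13.3% of genes, against 0.433% by chance. Of the 6 controls, 4 belong to the second series, and those had the highest sums of FPKM.

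Trophoblast genes in the ExE had no common direction. The list of ExE and trophoblast stem cell genes had a median of 0.03 and a mean of -0.03 (29 genes, 3 higher and 2 lower, 3 higher and 1 lower adjusted over the list alone, camera higher at adjusted p = 0.00247, adjusted p = 0.315 with an estimated correlation). Ets2, a trophoblast factor, rose from 25.5 to 53.8, and Tex19.1 fell from 290 to 130, a call lost after scaling (adjusted p = 0.16) and without control 4 or 5. Hand1, a factor of differentiating trophoblast, rose from 63.1 to 124 (1.07, with 0.10 in the first series and 1.70 in the second), and its call was lost without control 5, control 6, mzKO 3 or mzKO 5 (0.90 to 0.99 for Hand1 at the E6.5 ExE). Cdx2 was at 3.73 and 3.75 and Sox2 at 6.86 and 4.93, neither past the threshold and both of a sign that scaling turned positive, and Nr5a2 was listed at 0. The differentiated trophoblast list had a median of -0.47 and camera called it higher (11 genes, 4 higher and 2 lower, the same adjusted over the list alone, adjusted p = 0.0262, adjusted p = 0.459 with an estimated correlation). Without libraries that stood apart, camera's direction for this list reversed. Trophectoderm genes had a median of 0.004 (21 genes, 4 higher and 2 lower, the same adjusted over the list alone, camera adjusted p = 0.00205, adjusted p = 0.315 with an estimated correlation), and the galectin gene Lgals3 rose from 22.4 to 64.1. The DNA methylation and imprinting list had a median of 0.06 (23 genes, 6 higher and 5 lower, the same adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.315 with an estimated correlation).

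Cell cycle genes fell in the ExE beyond the shift of all genes. The list had a median of -0.89 (34 genes, 2 higher and 21 lower, 2 higher and 25 lower adjusted over the list alone, camera adjusted p = 0.00262, adjusted p = 0.459 with an estimated correlation). Plk1, a mitotic kinase gene, fell from 87.4 ± 29.0 to 24.6 ± 4.97 (-1.74, and -1.27 after scaling, past the threshold in both), and Rrm2 (320 to 117), Tyms (51.8 to 20.9) and Kif20a (31.5 to 10.8), genes of nucleotide supply and cell division, fell too. Oxidative phosphorylation genes had a median of -0.55 (84 genes, 30 lower, the same adjusted over the list alone, camera adjusted p = 0.00247, adjusted p = 0.667 with an estimated correlation), among them the complex I genes Ndufb10 (244 to 107), Ndufaf2 and Ndufs1 and the ATP synthase gene Atp5c1 (1038 to 328). Ribosomal protein genes had a median of -0.36 (74 genes, 2 higher and 14 lower, the same adjusted over the list alone, camera adjusted p = 0.932), and Rpl30 fell from 123 to 29.4. In the first series Rpl30 was at 36.5 and 56.5 FPKM in controls and 29.2 to 32.9 in mzKO libraries. In the second series it was at 134 to 192 in controls and 25.3 to 28.1 in mzKO libraries. Glycolysis genes had a median of -0.61 (24 genes, 5 lower, the same adjusted over the list alone, camera adjusted p = 0.862), and Tpi1 fell from 1306 to 578, a call lost after scaling. Cholesterol synthesis genes had a median of -0.25 (23 genes, 1 higher and 3 lower, the same adjusted over the list alone, camera adjusted p = 0.329), and Idi1, an isoprenoid isomerase gene, fell from 6.04 to 1.42.

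By camera, immediate early, p53 and Hippo-YAP genes were higher than other genes in the ExE. The immediate early and heat shock list was fixed in advance as genes that rise with handling and dissociation of tissue. Whether handling differed between the groups was not tested. Immediate early and heat shock genes had a median of 1.20 (16 genes, 7 higher and 1 lower, 8 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.95e-06, adjusted p = 0.315 with an estimated correlation), among them Jund (0.73 to 6.66). The p53 targets had a median of 0.38 (19 genes, 3 higher and 1 lower, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000205, adjusted p = 0.315 with an estimated correlation), and the cell cycle inhibitor genes Btg2 (2.93 to 9.40) and Cdkn1a (1.15 to 7.17) rose. Hippo-YAP targets had a median of 0.37 (13 genes, 2 higher, the same adjusted over the list alone, camera adjusted p = 8.81e-05, adjusted p = 0.315 with an estimated correlation), with the matrix protein gene Ccn1 going from 21.4 to 99.6. Integrated stress response genes had a median of -0.30 and a mean of 0.10 (15 genes, 3 higher and 4 lower, 3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0548), and Ppp1r15a, a phosphatase regulator of that response, rose from 3.59 to 26.0.

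Camera called 5 further lists in the ExE higher than other genes although their medians were negative. These were polarity and junction genes (median -0.22, 23 genes, 3 higher and 3 lower, the same adjusted over the list alone, adjusted p = 0.0389, adjusted p = 0.459 with an estimated correlation), naive pluripotency genes (median -0.43, 15 genes, 3 higher, the same adjusted over the list alone, adjusted p = 0.034, adjusted p = 0.459 with an estimated correlation) and primed epiblast genes (median -0.12, 23 genes, 2 higher and 1 lower, 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.034, adjusted p = 0.596 with an estimated correlation). The other two were primitive streak genes (median -0.23, 11 genes, 2 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.0262, adjusted p = 0.459 with an estimated correlation) and surface ectoderm genes (median -0.05 and mean 0.16, 9 genes, 1 higher, the same adjusted over the list alone, adjusted p = 0.0181, adjusted p = 0.347 with an estimated correlation). Genes behind these calls were Klf5 (6.62 to 23.8), the homeobox gene Cdx1 (0.20 to 3.79), the tight junction gene Tjp2 (12.4 to 24.7) and Tfap2a.

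The genotype effect differed between the E6.5 tissues for 84 genes, 27 more positive and 57 more negative in the ExE. Of these, 36 were below the level tested in 1 of the 2 tissues, so for them the difference restates the change in the other, as for Tfap2a, Cdx1 and Camk2a, which were below it in the epiblast. Tfap2a differed by 1.74, Cdx1 by 1.84 and Camk2a by 3.13 on the log2 scale, and Large2 by -2.69. This fit took all libraries as independent and held no series term, although pieces of the same embryo were correlated (estimated correlation 0.19). The count was larger with that correlation or with series as a term, as given in the section on processing. Leaving out any 1 control of either tissue, epiblast mzKO 1, 2, 3, 5 or 9 or ExE mzKO 1, 2 or 3 moved the count by more than 1.5 times, to values from 36 (without ExE control 4) to 1036 (without epiblast control 2). Between the 8-cell stage and the ICM the effect differed for 8 genes, 6 more positive and 2 more negative in the ICM, among them Flrt3 by 3.41, Vim by 4.00 and Dkk1 by 2.77. Of the 8, 5 were tested at only 1 of these stages, and these 3 only in the ICM. The count of 8 became 0 without 8-cell mzKO 1 or 3, 2 without ICM control 2, 5 without 8-cell control 3 and 13 without ICM mzKO 1, 3 or 5. Effects at the other stages were not tested against each other.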

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

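Chosen after their results were seen were the tests of scaling and of strain on the ExE and ICM patterns, of trophectoderm cells on the ICM pieces and of the series in the ICM. The other tests were written down before their results.

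4 changed-gene counts were set against other splits of the same libraries. At the 8-cell stage, 1 of 56 splits (the real one) gave 157 genes and the highest other gave 2, so chance can be excluded. In the ICM, 1 of 100 splits gave 73 and the highest other 9, and in the ExE 1 of 100 gave 2853 and the highest other 23, which excludes chance for both. The ExE split that follows the series gave 5. In the epiblast the real count was 0, 100 of 100 splits gave as many and the highest other gave 1. No split can fall below 0, so this comparison says nothing about chance. For gene lists, few splits gave as many in the ICM (12 lists, 4 of 100 splits, highest other 12) and in the ExE (14 lists, 2 of 100, highest other 14). Chance is thus unlikely for these counts but not excluded, since another split reached the real count in each. The counts say nothing about any single list. At the 8-cell stage (5 lists, 20 of 56, highest other 10) and in the epiblast (5 lists, 54 of 100, highest other 12) chance stays open. These splits exchange libraries between series. Splits within each series, with a series term, led to the same conclusions where the comparison could decide. For changed genes 1 of 24 splits gave 429 at the 8-cell stage (highest other 3), 1 of 36 gave 217 in the ICM (highest other 1), 1 of 100 gave 2764 in the ExE (highest other 8) and 100 of 100 gave at least the 0 of the epiblast, as any split must. For the count of lists, chance was unlikely in the ICM (14 lists, 1 of 36, highest other 13) and the ExE (14 lists, 3 of 100, highest other 14). It stayed open at the 8-cell stage (6 lists, 6 of 24, highest other 8) and in the epiblast (6 lists, 43 of 100, highest other 18). In the epiblast the split that set control 2 and mzKO 2, 3, 6 and 7 apart from the rest called 1994 genes, so these libraries differ by something other than the labelled genotype. They had the highest estimated relative depth of their series. It was 71.0%, 100% and 73.4% in control 2, mzKO 2 and mzKO 3 (others of the first series at most 56.5%). In mzKO 6 and 7 it was 46.9% and 49.2% (others of the second series at most 40.7%). Whether depth made the difference was not tested.

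In the E6.5 ExE, many more genes were lower than higher in libraries labelled mzKO, with 2528 lower and 325 higher. Unequal shares of the groups in the 2 series did not alone make the shift of all genes, since their median was negative in both and at most -0.37 in either. The excess of calls was found in the second series alone (199 higher, 2378 lower) and not in the first (16 higher, 10 lower). At an unadjusted p below 0.05 the first gave 528 higher and 1552 lower genes, and the second 437 and 3546, so both leaned lower. Whether the excess of calls comes from the controls of the second series stays open. Unequal scaling of the libraries cannot be told apart from a general fall as the source of the excess. After median-of-ratios scaling 48.3% of the calls were higher, but that step centres the genes and so sets this share by itself. Scaling was not the whole cause of 1049 of the 2853 changed genes, which were called in the same direction after it (323 higher, 726 lower), where no other split of the scaled values called more than 297 genes and the split by series 9. For the remaining 1804, of which 1802 were lower, scaling cannot be told apart: their median absolute log2 difference went from 1.04 (median standard error 0.30) to 0.61 (0.277), so their calls ended because the difference shrank, as a shift of all genes would give. RNA of epiblast or visceral endoderm in control libraries 3, 5 and 6, which had the highest mean of primed epiblast genes, cannot be told apart from a genotype effect: the 1892 genes at least 2-fold lower against those controls had a median -0.46 relative to all genes in the other libraries, but those are not free of such RNA, with visceral endoderm markers at 329 FPKM in mzKO 5 and 221 in control 4 (208, 309 and 382 in controls 3, 5 and 6), so this value decides nothing. Without those 3 controls and mzKO library 1, 186 genes changed. The headers of all second-series controls name WT, and another strain in them cannot be told apart either: the 2782 genes at least 2-fold lower in the second series had a median -0.23 relative to all genes in the first, between the bounds of -0.2 and -0.5. A difference in RNA quality stays open too, since Lars2 was at 208 to 1497 FPKM in controls and 3177 to 16985 in mzKO libraries, with a difference of 3.36 in the first series and 3.69 in the second. Handling of the pieces was not tested either, and the immediate early list, whose genes rise with handling, was higher by camera. A genotype effect stays open.

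In the E3.5 ICM, pluripotency genes were lower and primitive endoderm genes higher in libraries labelled mzKO. Trophectoderm cells left on the control pieces would dilute, in controls, naive genes that trophectoderm expresses less. Naive genes were instead lower in mzKO libraries (median -0.86), opposite to such dilution. That median is the pattern itself, and the level of the list in trophectoderm was not compared. Nanog averaged 105 FPKM in ICM controls and 37.5 ± 29.6 in the 2 E4.5 TE controls. Trophectoderm cells would also dilute primitive endoderm genes in controls, and as a part of the rise of those genes they stay open. The log2 difference of the trophectoderm list minus that of all genes was -0.091, which decides nothing. Krt18 was at 695 FPKM in controls and 219 in mzKO libraries. Were unequal scaling the whole cause, scaling would bring the median of the naive list above -0.2, and it was -0.52. A difference between series did not make the pattern, since each series holds as many control as mzKO libraries, the naive list was at most -0.56 and the endoderm list at least 0.21 in each, and both passed camera with a series term and the preset correlation (adjusted p = 1.79e-05 and 9.63e-10). With an estimated correlation, and no series term, neither list passed camera. The headers of controls 2 and 3 name B6, but another strain in them was not the whole cause, since without the second series the medians were -0.79 and 0.54. The strain of the other libraries is not given, and culture of the embryos was not tested. A difference in RNA quality stays open, since Lars2 averaged 1959 FPKM in controls and 5140 in mzKO libraries, although in the third series, where Lars2 differed by 0.42, Nanog differed by -3.05 and Gata4 by 2.37. A shift of ICM cells from epiblast to primitive endoderm stays open as a hypothesis and was not tested, since whole pieces were sequenced. Visceral endoderm genes, with a median of 0.07, did not rise along.

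From the 8-cell stage on, Tfap2c overlapped between the groups as labelled. Control embryos under a mzKO label would sit among the controls on an axis from the control mean to the mzKO mean, built without the library tested. The lowest mzKO library was at 0.15 at the 8-cell stage, where the highest control was at -0.51, at 0.063 in the ICM (highest control -0.27) and at 0.295 in the ExE (highest control -0.10), so no mzKO library of these 3 stages sat among controls. Libraries of the TE and the epiblast were not tested this way. Reads from outside a deleted part of the gene stay open, since the files hold 1 value per gene (mzKO over control 0.828 at the 8-cell stage). For this reason directions from the 8-cell stage on rest on the labels.

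The genotype effect differed between 2 tissues or stages for the genes below, by limma's interaction test. For the E6.5 tissues 84 genes passed, and with 1 library left out the count ran from 36 to 1036. Of 100 relabelled sets 2 gave as many, the real one included, and the highest other gave 87. That share is below the 0.05 level, but another set gave more genes than the real labels. Genotypes were redrawn within each tissue, which also separates pieces of the same embryo, so chance is not excluded. Of the 84, 36 were below the level tested in 1 of the tissues, so for them the difference restates the change in the other. More positive in the ExE were Arsi, a sulfatase gene (1.99), Tfap2a (1.74), Camk2a (3.13), Cdx1 (1.84) and Ckap4 (2.22). More negative were 3830417A13Rik (-3.35), the integrin gene Itga7 (-1.97), the virus receptor and junction gene Cxadr (-1.77), Large2 (-2.69) and Aif1l (-2.66). Of these 10, only Ckap4, Cxadr, Large2 and Aif1l were tested in both tissues. Between the 8-cell stage and the ICM 8 genes passed (1 of 100 sets, highest other 7, which excludes chance; the count was 0 without 8-cell mzKO 1 or 3). More positive in the ICM were Flrt3 (3.41), the calmodulin-like gene Calm5 (2.35), Slc22a13b (3.75), Vim (4.00) and Dkk1 (2.77), and more negative Snx12 (-3.12) and Khdc1b (-3.23). Only Slc22a13b, Snx12 and Khdc1b were tested at both stages. Flrt3, Vim and Dkk1 were below the level tested at the 8-cell stage and Calm5 below it in the ICM, so its difference reflects a lower value at the 8-cell stage in mzKO libraries.

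12 of 147 groups tested by Dixon's rule had a single library far from the rest, where chance gives about 1 in 20 groups. At the 8-cell stage these were control 4 for Usp17lb (3.20 FPKM, others at most 0.304) and Ecscr (1.18, others 0), control 3 for Serinc2 (0.857, others at most 0.126) and control 5 for Fgf5 (0.097, others 1.13 to 1.77). In the ICM they were control 1 for Cdx2 (5.83, others 19.6 to 28.0) and for the share of ribosomal precursor Rn45s (7.13% of the FPKM sum, others 0), mzKO 3 for Aqp8 (171, others 56.9 to 74.9) and mzKO 4 for Mt4 (2.11, others 0). In the epiblast they were control 4 for the share of Rn45s (9.0%, others 0) and mzKO 1 for that of Lars2 (15.6%, others 0.569 to 6.00). In the ExE they were control 1 for Psors1c2 (0.250, others 8.43 to 25.5) and control 2 for Reep6 (96.4, others 18.0 to 29.1). Without mzKO 3, Aqp8 at the E3.5 ICM still passed.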

How the results depend on the processing

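Chosen after seeing the data were the series term, each series alone, the series term within the interactions, the correlation between pieces of 1 embryo, the crossed numbers, the alternatives for shared genes and the sets without libraries that stood apart. The other alternatives were planned. The cause of a change was not tested unless stated.

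For 295 pairs of a named gene and a stage, 4288 of the results over all alternatives kept direction and side of the threshold, 439 fell short of it, 121 newly passed it and 18 reversed. For the 58 pairs of a described gene list and a stage these numbers were 802, 184, 17 and 19. H19, Igf2, Tfap2a and Plk1 in the ExE passed under each alternative run, and Nanog and Gata4 in the ICM under each except no filter.

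Changed genes at the 2-cell stage (3) came to 0 with a pseudocount of 0.1, 0 with no filter and 0 with scaling. With all 14 groups in 1 fit, where spread is shared, the counts were 437 at the 2-cell, 719 at the 4-cell (main 0), 328 at the 8-cell (157), 473 in the ICM (73) and 941 in the TE (0). Tfap2c then passed at the 4-cell stage (-2.27) and in the ExE (1.08). In that fit 1 list passed at the 4-cell stage (main 5) and 1 in the TE (main 3). With no filter, 37 genes changed at the 8-cell stage and 3 in the ICM, where more genes are tested. Lists past the threshold were then 3 at the 4-cell stage, 5 in the TE, 9 in the epiblast (main 5) and 9 in the ExE (main 14). In the ICM the count was 25 with a pseudocount of 0.1, 42 with scaling and 618 with array weights.

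Scaling gave 1403 genes in the ExE (2853), 5 lists in the TE and 9 in the ExE, Tfap2c at 1.54 in the ExE (past the threshold) and Tfap2c at 0.022 in the ICM (reversed). Array weights gave Tfap2c 1.26 in the ExE (past) and 9 lists there. With an estimated correlation 0 lists passed at each of the 7 stages.

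With the replicate block (numbers taken as pairs, which the data did not bear out), 0 genes changed at the 2-cell stage, 1 at the 8-cell stage, 2 in the TE and 1 in the epiblast, and 5 lists passed in the TE. Reversed under this pairing block were Cdx2 at the 8-cell stage (0.32), the primed epiblast list in the epiblast (0.13) and Sox2 in the ExE (0.12). Crossed numbers as a block gave 4 genes at the 2-cell stage.

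A series term gave 429 genes at the 8-cell stage and 217 in the ICM. The first series alone gave 0 at the 8-cell stage, 1 in the epiblast and 26 in the ExE, where Tfap2c reversed (-0.26). The second series alone gave 49 at the 8-cell stage, 18 in the ICM, 3 in the epiblast and Tfap2c at 1.81 in the ExE (past), and the third 238 in the ICM with Tfap2c at 0.22 (reversed). Without libraries that stood apart, 91 genes changed at the 8-cell stage and 186 in the ExE, and 11 lists passed in the epiblast. Fewer libraries were compared in these sets.

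For the interaction of the E6.5 tissues (84), the count was 22 with a pseudocount of 0.1, 131 with scaling, 2762 with array weights, 716 with series as a term and 300 with a correlation between pieces of 1 embryo. For the 8-cell stage and the ICM (8) it was 2 with a pseudocount of 0.1, 22 with no filter, 85 with array weights and 44 with series as a term.

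Shared higher genes of the 8-cell stage and the ICM (0) came to 5 with all 14 groups, 6 with array weights and 4 with a series term, all past the threshold. Shared higher genes of the ICM and the ExE (1) came to 5 with all 14 groups. Shared lower genes of the ICM and the ExE (13) came to 80 with all 14 groups, 223 with array weights and 5 without libraries that stood apart, each past the threshold. Shared lower genes of the 8-cell stage and the ExE (13, below chance) were 5 with scaling, 5 with no filter and 2 without libraries that stood apart, and both of the latter lay above chance.

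Leaving out 1 library at a time gave 0 to 0 changed genes at the 2-cell stage, 28 (without mzKO 1) to 142 at the 8-cell stage, 26 (without control 2) to 74 in the ICM and 1942 to 3074 in the ExE. Tfap2c ran from -0.65 to 0.12 at the 8-cell stage (0.12 without mzKO 1), from -0.075 (without control 1) to 0.080 in the TE (-0.01 without mzKO 1) and from 0.91 to 1.35 in the ExE. Lists past the threshold ran from 2 to 4 at the 2-cell stage, 0 to 7 at the 4-cell stage, 3 to 6 at the 8-cell stage, 10 to 19 (without mzKO 2) in the ICM, 0 to 3 in the TE, 5 to 8 in the epiblast and 10 to 15 in the ExE. The interaction counts ran from 36 (without ExE control 4) to 1036 (without epiblast control 2) for the E6.5 tissues and from 0 (without 8-cell mzKO 1) to 13 for the 8-cell stage and the ICM. Shared genes ran from 0 to 1 (higher, 8-cell and ICM), from 2 (without ICM control 2) to 10 (lower, 8-cell and ICM, main 9), from 3 (without ICM control 2) to 15 (lower, ICM and ExE, main 13), from 0 to 2 (higher, 8-cell and ExE), from 6 to 14 (lower, 8-cell and ExE, with 6 and above chance without 8-cell mzKO 1) and from 1 to 2 (higher, ICM and ExE). Where this left 1 library in a group, it was assumed to vary like the others.

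Other reversals, where a list's value is its median and its direction is camera's, were as follows. At the 4-cell stage the list of the 2-cell program reversed with no filter (0.027), with all 14 groups (0.047), and without control 2 (-0.073), mzKO 1 (-0.04) or mzKO 2 (0.41). The oocyte list reversed without control 2 (0.56) or mzKO 2 (0.73, lowest -0.81), and Nr5a2 without control 2 (0.30, lowest -0.78). At the 8-cell stage the trophectoderm list (0.39, lowest -0.48) and Cdx2 (0.24, lowest -0.62) reversed without mzKO 1, and Cdx2 without control 4 (0.08). In the ICM Nr5a2 reversed with scaling (0.17). The primed epiblast list reversed in the epiblast without libraries that stood apart (0.14).

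In the ExE, ribosomal genes reversed with no filter (-0.35), array weights (-0.47) and without control 1 (-0.46), control 2 (-0.44) or mzKO 5 (-0.46, highest -0.28), and glycolysis genes with scaling (-0.16) and without control 2 (-0.56) or mzKO 1 (-0.50, lowest -0.75). The differentiated trophoblast list reversed without libraries that stood apart (-0.71). Cdx2 reversed with scaling (0.18), array weights (0.043) and without mzKO 4 (0.12). Sox2 reversed with a pseudocount of 0.1 (0.11), scaling (0.28), a series term (0.36) and without libraries that stood apart (1.46), and ran from 0.10 to 0.33 without control 3, 5 or 6 or mzKO 1 or 5 (lowest -0.43). These lists and genes had not passed the threshold except differentiated trophoblast.

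The files hold no counts, so the number of reads behind small FPKM values is unknown. The estimated relative depth was lower in both mzKO libraries of the TE than in both controls. In the ICM it was lowest in mzKO 1 (29.9%). Groups of 2 libraries called 0% of simulated 4-fold changes, so low counts at the 2-cell, 4-cell and TE stages exclude little.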

Other observations

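The tests of late development were written down before their results were seen.

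Genes of the 2-cell program differed both ways at the 4-cell stage. Arg2 was higher in mzKO libraries at both stages (22.2 and 73.4 FPKM at the 2-cell stage, 4.75 and 29.8 at the 4-cell stage). At the 4-cell stage Usp17la was higher as well (0.23 and 4.75), Tdpoz3 (14.5 and 0.69) and Tcstv3 (35.3 and 8.05) were lower, and among oocyte genes Bcl2l10 was at 45.5 and 7.05 and the zona pellucida gene Zp1 at 6.55 and 1.67. None of these passed over all genes tested.

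In the ExE, marker genes of the primed epiblast had their highest mean log2(FPKM + 1) in controls 3, 5 and 6 (3.6, 3.51 and 3.41, others 2.12 to 3.24). Their sum of FPKM was highest in controls 4, 5 and 6 (1714, 1840 and 1799, others 474 to 947). Visceral endoderm markers summed to 208, 221, 309 and 382 FPKM in ExE controls 3, 4, 5 and 6 and to 329 in mzKO 5, which stood apart from the other mzKO libraries (74.4 to 218). In the epiblast, these markers summed to 217, 148, 283 and 299 FPKM in mzKO libraries 1, 4, 9 and 10 and to at most 99.1 in the other libraries. Mixl1, a gene of the primitive streak, was at 7.78 ± 9.12 in control and 0.57 ± 0.77 in mzKO ExE libraries, with 0.08 in the first series and -2.74 in the second on the log2 scale.

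A hypothesis of late development was tested: if mzKO embryos reach a later control state late, genes lower in them should more often rise between earlier and later controls, and genes higher in them should more often fall. Controls of the compared stage itself were left out of this axis. At the 8-cell stage 34.9% of the lower genes rose at least 2-fold from the 4-cell to the ICM controls, against 23.8% of other genes (Fisher's exact test, two-sided adjusted p = 0.0123 over 4 tests), and 45.8% of the higher genes fell, against 23.9% (adjusted p = 0.00396). In the ICM 23.1% of the lower genes rose from the 4-cell to the 8-cell controls, against 10.2% (adjusted p = 0.0123), but 19% of the higher genes fell, against 21.1% (adjusted p = 1). The median change along the axis was -0.77 for the higher 8-cell genes (others 0), -0.05 for the lower 8-cell genes (others 0) and 0.11 for the lower ICM genes (others -0.20). Late development may thus account for part of the genes higher at the 8-cell stage. The lower 8-cell genes had a median near 0, so genes that change much in either direction would give the same result, and the genes that rose in the ICM give no sign of a delay. The stages were also sequenced in different series.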
